A study of Arabidopsis thaliana with 24 samples.

How the data were processed

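Expression was measured in roots and shoots of 7 d old Arabidopsis thaliana seedlings of the line the labels call ulox, after 1 h in water or after 1, 2 or 3 h in 30% PEG. The labels name MARS-seq, which tags the 3′ ends of transcripts, and 75 cycles on an Illumina NextSeq. The 24 libraries were grouped by their source names, which give tissue, treatment and hours, into 8 groups of 3 replicates. A separate tissue field, which reads root for every sample, was not used. The sample titles code the water libraries as time 0, while their source names say 1 h, and the source names were followed.

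The authors' deposited table holds raw counts per gene and library, and these counts are the input of every test made here. The authors' normalized signal, named so in the file headers, is by its values the same counts divided by 1 size factor per library. Its 24 columns were not used. The deposited log2 fold changes compare named groups, with their sign read from the raw counts, and each deposited p-value is adjusted per the file headers. Of the 28 deposited comparisons 9 match a contrast made here and were set beside it, and 19 were not used here. The authors' deposited table also marks each gene as called or not, by a rule not given in the sources used here. In the comparisons used, each of the authors' calls has an absolute log2 of at least 1.0002 and an adjusted p under 0.05, so the like count here is the one at an absolute log2 of at least 1. As both start from the same counts, a like sign is no independent support for either. The submitters' processing notes name bcl2fastq, cutadapt, STAR 2.4.2a, HTSeq and DESeq2, with no order and no other version. The genome build, the annotation, the strand used in counting and whether molecular identifiers were collapsed are not given in the sources used here. For that reason no gene positions are printed.

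The table lists 14557 genes, each with at least 6 counts in some library, and 0 of the counts are not whole numbers. Gene names, products and overlaps were taken from a gene table of the TAIR10.1 assembly, which may differ from the authors' annotation. It matched 14457 of the locus codes, and the 100 organelle codes, 67 of the chloroplast and 33 of the mitochondrion, were not matched. Library totals ran from 1203312 to 7029587 counts, with 11638 to 14012 genes that had a count. Where a gene had 1 to 3 counts in an arm, its ratio is given with a 95% counting interval, which covers counting error alone. Where an arm had 0 counts no fold is printed and the list median was also taken at a floor of 3 counts over the group. Beyond that, precision is given as the SD over replicates.

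Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (1.17.8). Genes were filtered with edgeR's filterByExpr, counts were scaled by TMM, and negative binomial quasi-likelihood models with robust dispersion were fitted. PEG against water, and 3 h against 1 h, were tested in a fit of the 12 libraries of a tissue, with 9751 genes in root and 9207 in shoot. The root change minus the shoot change, and root against shoot in water, were tested in a fit of all 24 libraries with 10967 genes. Tests are two-sided, and a gene is called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast, 12 contrasts in all. The biological coefficient of variation was 34.2% in root and 17.2% in shoot. Levels are TMM-scaled CPM of the fit in question, so a root value in water differs slightly between the root fit and the fit of both tissues. The pairs of replicate libraries differed by more than counting noise, with chi-square per degree of freedom from 2.30 to 35.3, so none were duplicates.

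The contrasts, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The naming rule took, per tissue and PEG time, the 5 largest rises and 5 largest falls among called genes with a mean count of at least 20 and no overlap between PEG and water libraries. It also took the 2 members of each list with the smallest adjusted p in each tissue, 4 genes in each direction for each tissue difference, 6 lipoxygenases, and RBCS1A, CAB3, PYK10 and CASP1 as checks of the tissue labels. Other list members, and genes in the plot of single genes, were picked as examples after their values were seen. The 23 lists hold 357 genes, of which 310 are in the table, 253 were tested in root and 256 in shoot. Each list was tested against all other genes with camera on voom values at a preset correlation of 0.01, adjusted over the 23 lists of a contrast, and again with an estimated correlation. Over the 6 comparisons of PEG with water the preset gave 59 calls and the estimated correlation 2. The fry test, which asks whether a list's own genes move one way on balance without comparing them with other genes, gave 41. The list of genes induced by singlet oxygen, like the others, was written from general knowledge, and no list was chosen on these samples.

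Alternatives were DESeq2's size factors (RLE) in the same fit, DESeq2's Wald test, no low-count filter, a filter at a mean of 10 counts, an absolute log2 fold change of at least 1, organelle genes left out, a block of replicate letters or seedling pools, a joint fit of both tissues, a fit of the 6 libraries compared, and each library left out in turn. After the data were seen, voom with sample quality weights, scaling by library totals, and leaving out root water B with root PEG 2 h A were added. The pipeline was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold for each of the contrasts below. It recovered 47% of changes of 2-fold and 82% of 4-fold in shoot at 3 h, 7% and 51% in root at 3 h, 3% and 34% for the tissue difference at 3 h and 13% and 58% for root against shoot in water, with 1 to 3 false calls. An abscisic acid list planted at 2-fold was called, and 0 of the other lists were. The genes were simulated independently of each other, so this does not test list calls where the genes of a list correlate. Other splits of the samples were counted as well, all 10 for contrasts of 3 with 3 libraries and 50 for each tissue difference.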

Results

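RNA was measured in Arabidopsis thaliana seedlings that the labels call ulox, a name the labels do not define. Seedlings 7 d old grew with 16 h of light and 8 h of dark at 21 °C on medium with 1% sucrose. They were then placed in water for 1 h or in 30% polyethylene glycol (PEG), an osmotic agent that withholds water at -2.0 MPa, for 1, 2 or 3 h. Roots and shoots were separated after the treatment, and each biological replicate held 30 to 50 seedlings. The 24 libraries, made by MARS-seq, a method that counts the 3′ ends of transcripts, form 8 groups of 3 replicates (A, B and C). Total counts per library ran from 1597302 to 7029587 in root (median 3010694) and from 1203312 to 6090852 in shoot (median 3024691). No wild type was sampled, so every comparison lies within ulox. By the source names water was sampled at 1 h alone, so the 2 h and 3 h comparisons also differ from their control in time of day and time in liquid. The sample titles code the same water libraries as time 0. If the titles hold, the 1 h comparison differs from its control in time as well. The comparisons of 3 h with 1 h of PEG also differ in time of day and time in liquid. All 3 PEG times of a tissue share its 3 water libraries, so their results are not independent of each other. Levels are CPM with trimmed-mean (TMM) scaling, as mean ± SD over n = 3 libraries, and changes are log2 fold changes from edgeR's quasi-likelihood fit with Benjamini-Hochberg adjusted p.

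The lipoxygenases open the account because the name ulox holds their gene symbol, LOX, although the labels do not say what the name stands for. Tags from outside any altered part of a gene would not show an alteration. LOX2, the chloroplast 13-lipoxygenase of wound-induced jasmonate synthesis, rose in shoot at 3 h, from 109 ± 15.7 in water to 188 ± 17.0 (log2 0.80, SE 0.19, adjusted p = 0.00594). LOX3, another 13-lipoxygenase, rose from 42.8 ± 9.44 to 67.1 ± 12.6 at 1 h (log2 0.68, adjusted p = 0.0471) and to 73.4 ± 23.2 at 3 h (log2 0.76, adjusted p = 0.0218). At 2 h LOX3 stood at 56.7 ± 5.56 (adjusted p = 0.294). LOX1, LOX4 and LOX6 lay between log2 -0.64 and 0.16 at the 3 times in shoot, none called, and LOX5 had 92 counts over the 12 shoot libraries and was not tested. In root LOX2 had 2 counts over 12 libraries, 11 of them without a count, and none of the other 5 genes was called. The largest root value was that of LOX3 at 1 h, 6.05 ± 3.25 against 1.85 ± 1.65 in water (log2 1.62, adjusted p = 0.351). In water, root against shoot, LOX3 was lower (log2 -4.83), as were LOX6 (-1.79) and LOX4 (-1.48), while LOX1 (1.23) and LOX5 (1.63) were higher. Of the 5 lipoxygenases tested in shoot at 3 h, 2 rose, 0 fell and 3 were not called, with 2 and 0 adjusted over the list alone (median log2 0.16, camera adjusted p = 0.323). The LOX2 call was lost in the joint fit of both tissues, and the gene's change was below log2 1. The LOX3 call at 1 h was lost without shoot PEG 1 h A (adjusted p = 0.12), PEG 1 h B (0.129), water A (0.147) or water C (0.137). Its call at 3 h was lost without shoot PEG 3 h A (0.115), water A (0.0812) or water C (0.0791).

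Root and shoot in water were compared to see whether the libraries carry the tissue their labels name, since a tissue field in the labels reads root for all 24. RBCS1A, a Rubisco small subunit, stood at 161 ± 93.9 in root and 36614 ± 1006 in shoot (log2 -7.84). CAB3, a light-harvesting protein of photosystem II, stood at 13.3 ± 5.21 and 16025 ± 3312 (log2 -10.30). CASP1, which builds the Casparian strip of the root endodermis, stood at 451 ± 163 in root and 6.61 ± 1.77 in shoot (log2 6.04). PYK10, a beta-glucosidase of endoplasmic reticulum bodies, did not separate the tissues, at 81.1 ± 14.2 and 46.4 ± 28.0 (log2 0.80, adjusted p = 0.188). All 34 photosynthesis genes tested were lower in root, and 34 adjusted over the list alone (median log2 -7.65, camera adjusted p = 2.76e-32, or 0.055 with an estimated correlation). Of 16 root cell type genes 14 were higher in root, 0 lower and 2, PYK10 and SCR, not called, with 14 adjusted over the list alone. Their median was 5.57, or 4.87 with RHD6 and COBL9, which had no count in shoot water, set at 3 counts over the group (camera adjusted p = 1.78e-07, or 0.012 with an estimated correlation). Photosynthesis genes took 23.2 to 28.7% of counts in the 12 shoot libraries and 0.204 to 0.502% in the 12 root libraries. Of 10967 genes tested, 5845 differed, 2977 higher and 2868 lower in root. With library totals in place of TMM the median of all genes rose to 0.28 and the share of calls higher in root from 50.9 to 62.3%. Aquaporins had 11 members higher, 4 lower and 4 not called in root (11 and 4 adjusted over the list alone, camera adjusted p = 0.0318, or 0.727 with an estimated correlation), a call lost without root water B (adjusted p = 0.181). Phenylpropanoid genes had 7 of 10 higher and 3 not called, with 7 adjusted over the list alone (camera adjusted p = 0.00733, or 0.437 with an estimated correlation). Expansins and xyloglucan endotransglucosylases had 0 higher, 5 lower and 2 not called, with 0 and 5 adjusted over the list alone (camera adjusted p = 0.0318, or 0.574 with an estimated correlation).

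**Figure D1:**
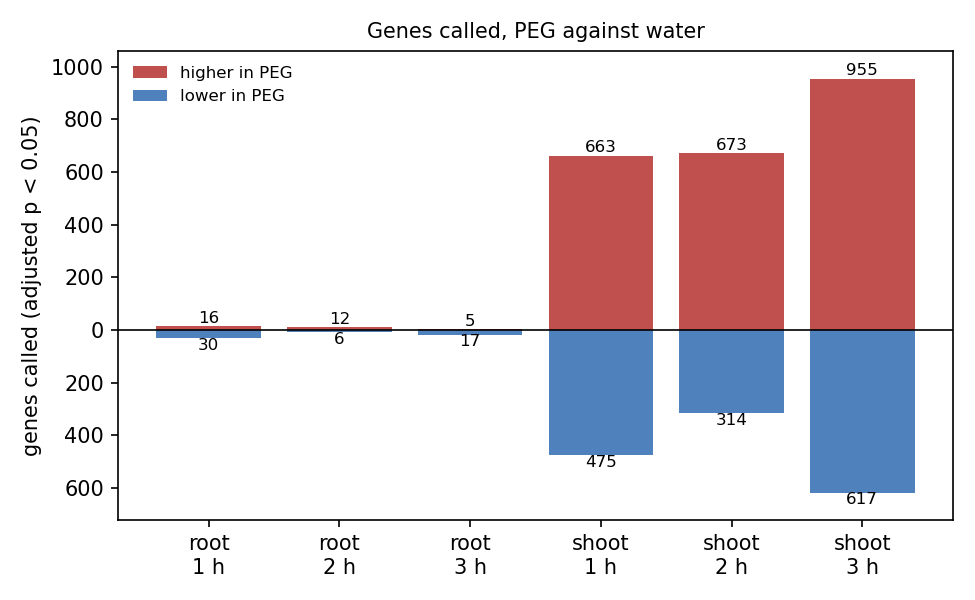
Genes called in edgeR's quasi-likelihood test at an adjusted p under 0.05 for PEG against water, by tissue and hours in PEG, where bars above 0 count genes higher in PEG and bars below 0 genes lower in PEG. Shoot counts run from 987 to 1572 and root counts from 18 to 46.

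Genes for proteins that protect dehydrated cells rose in shoot after 3 h of PEG. RD29A (LTI78), a hydrophilic protein induced by drought and cold, rose from 137 ± 29.1 to 2578 ± 165 (log2 4.24, SE 0.20, adjusted p = 4.39e-11). COR15A, which protects chloroplast membranes, rose from 26.0 ± 5.70 to 1119 ± 151 (log2 5.42), and the dehydrin XERO2 from 35.3 ± 5.61 to 684 ± 24.03 (log2 4.27). ERF53, a drought-induced transcription factor, rose from 2.35 ± 0.558 to 160 ± 12.7 (log2 6.11), and AT4G28140, of the same family, from 1.91 ± 0.686 to 93.7 ± 6.99 (log2 5.61). At the other end, EXO, a protein of brassinosteroid-promoted growth, fell from 503.8 ± 56.7 to 59.1 ± 3.16 (log2 -3.08), and AT1G33760, another ERF-family factor, from 59.6 ± 3.19 to 3.08 ± 0.567 (log2 -4.29). Falls were also called for the zinc-finger protein ZF3 (log2 -3.01), the wound-responsive protein gene AT4G33560 (-3.06) and the pectin methylesterase gene AT2G26440 (-2.81). AT1G70640, a PB1 domain protein, had 122 counts in PEG and 1 in water, a ratio of 114 (counting interval 20.13 to 4551). COR15A and COR15B are near-identical, so reads may be shared between them.

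Of the 16 dehydration genes tested at 3 h in shoot, 12 rose, 1 fell and 3 were not called, with 13 and 2 adjusted over the list alone (median log2 2.89, camera adjusted p = 1.41e-14, or 0.106 with an estimated correlation). RD26, a NAC factor of the abscisic acid response, rose from 14.8 ± 4.07 to 443 ± 23.2 (log2 4.87) and KIN1 by log2 3.93, while ERD1, a chloroplast protease subunit, fell (log2 -0.70). Of 22 abscisic acid genes 13 rose, 4 fell and 5 were not called, with 14 and 4 adjusted over the list alone (median log2 1.42, unchanged with HAI2, which had no count in water, set at 3 counts over the group, camera adjusted p = 4.89e-05, or 0.127 with an estimated correlation). Those that rose include NCED3, which makes the hormone's precursor (1.51 ± 1.29 to 18.5 ± 0.754, log2 3.51), and ABI1, a phosphatase that holds the pathway back (77.1 ± 4.55 to 514 ± 32.4, log2 2.74). The 4 that fell are all receptors of the hormone: PYL4 went from 612 ± 30.1 to 90.0 ± 16.1 (log2 -2.74), with PYL6 at -2.81, PYL5 at -1.73 and PYR1 at -1.35. Of 11 DREB, CBF and ZAT factors 6 rose, 1 fell and 4 were not called, with 6 and 2 adjusted over the list alone (median log2 0.95, camera adjusted p = 0.0129, or 0.431 with an estimated correlation). CBF3, a cold and drought regulator, rose from 5.10 ± 0.894 to 191 ± 88.3 (log2 5.23) and the zinc-finger factor ZAT6 from 33.4 ± 4.67 to 221 ± 44.3 (log2 2.71). SZF1, a salt-induced zinc-finger gene, fell from 251 ± 8.51 to 72.2 ± 7.30 (log2 -1.81). Of 8 compatible-solute genes 3 rose, 1 fell and 4 were not called, with 3 and 1 adjusted over the list alone (median log2 0.39, mean 1.18, camera adjusted p = 0.0275, or 0.133 with an estimated correlation). P5CS1, of proline synthesis, rose from 20.02 ± 5.73 to 161 ± 28.0 (log2 3.00) and GolS3, of raffinose synthesis, from 2.31 ± 1.54 to 72.4 ± 9.58 (log2 4.92). ERD1's call was lost without any library but shoot water C (highest adjusted p = 0.152, without water B), and the solute list's without shoot water C or PEG 3 h C (highest adjusted p = 0.0542). The solute list's median was 0.62 without water A and 0.21 without water B.

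Among hormone and signalling lists in shoot at 3 h, 11 of 21 jasmonate genes rose, 2 fell and 8 were not called, with 12 and 3 adjusted over the list alone (median log2 0.59, camera adjusted p = 0.00788, or 0.249 with an estimated correlation). AOC1 and AOC2, near-identical allene oxide cyclases that act after the lipoxygenases, rose from 46.5 ± 5.69 to 160 ± 23.5 (log2 1.77) and from 252 ± 25.7 to 625 ± 103 (log2 1.31). Among 8 genes known from singlet oxygen treatments 0 rose, 4 fell and 4 were not called, with 0 and 4 adjusted over the list alone (median log2 -0.85, camera adjusted p = 0.000310, or 0.166 with an estimated correlation). The defence regulators WRKY33 and WRKY40 fell from 129 ± 22.6 to 35.5 ± 8.38 (log2 -1.81) and from 116 ± 5.58 to 34.6 ± 1.74 (log2 -1.75). Of 8 touch and wound genes 1 rose, 7 fell and 0 were not called, with 1 and 7 adjusted over the list alone (median log2 -1.93, camera adjusted p = 9.07e-06, or 0.106 with an estimated correlation). ERF104 and ERF105, early ethylene response factors, fell (log2 -1.84 and -2.25), and ERF4, a repressor, rose (log2 0.87). Ethylene genes split, with 2 rising, 2 falling and 6 not called of 10, and 2 and 2 adjusted over the list alone (median log2 -0.19 with an upward test, camera adjusted p = 0.981). ERS2, an ethylene receptor, rose from 9.11 ± 3.23 to 23.0 ± 0.600 (log2 1.34). Of 7 salicylic acid and camalexin genes 0 rose, 1 fell and 6 were not called, with 0 and 1 adjusted over the list alone (median log2 -1.11, camera adjusted p = 0.0647). Auxin genes had 0 rising, 2 falling and 7 not called of 9, with 0 and 3 adjusted over the list alone (median log2 0.00, or -0.03 with library totals, mean -0.08, a downward test, camera adjusted p = 0.272). AUX1, an auxin importer, fell (log2 -0.91).

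Clock genes rose together in shoot, with 8 of 12 rising, 0 falling and 4 not called at 3 h, and 9 and 0 adjusted over the list alone (median log2 1.13, camera adjusted p = 5.51e-09, or 0.0223 with an estimated correlation). ELF4, of the evening complex, rose from 13.8 ± 3.85 to 310 ± 10.7 (log2 4.52, adjusted p = 1.3e-10). LUX, of the same complex, rose from 63.5 ± 13.4 to 207 ± 27.2 (log2 1.71), and PRR5, a clock repressor, from 20.6 ± 1.35 to 107 ± 4.72 (log2 2.38). Dark and low-sugar genes had 4 of 9 rising, 0 falling and 5 not called, with 4 and 0 adjusted over the list alone (median log2 0.57, or 0.90 without shoot water B, camera adjusted p = 0.00455, or 0.133 with an estimated correlation). DRM1 (DYL1), a dormancy-associated gene, rose from 155 ± 28.9 to 387 ± 29.6 (log2 1.32). Of the 10 low-oxygen genes 2 rose, 5 fell and 3 were not called, with 2 and 7 adjusted over the list alone (median log2 -1.004, camera adjusted p = 0.0807). Those that rose are enzymes of fermentation and sucrose use, ADH1 from 6.91 ± 2.48 to 78.8 ± 12.7 (log2 3.46) and SUS1 from 4.04 ± 0.459 to 19.9 ± 3.21 (log2 2.23). Those that fell are the oxygen sensor PCO1 (log2 -2.65), the repressor HRA1 (-2.13), the desaturase SAD6 (-1.73), the ethylene response factor HRE1 (-1.03) and the haemoglobin HB1 (-0.98). Calls were lost for PCO1 without shoot PEG 3 h B (adjusted p = 0.0594), for HRE1 without PEG 3 h B (0.0585) or C, and for SAD6 without water C (0.134) or any 3 h PEG library.

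Aquaporins in shoot at 3 h had 5 of 18 rising, 1 falling and 12 not called, with 5 and 3 adjusted over the list alone (median log2 0.06, mean -0.07, camera adjusted p = 0.562). PIP2A, a plasma membrane water channel, rose from 572 ± 19.9 to 1142 ± 153 (log2 1.00). Heat shock genes had 3 of 7 rising, 0 falling and 4 not called, with 4 and 0 adjusted over the list alone (median log2 0.68, camera adjusted p = 0.0312, or 0.133 with an estimated correlation), the small chaperone HSP17.6C (AT1G53540) at log2 1.66. Phenylpropanoid genes had 3 of 9 rising, 0 falling and 6 not called, with 4 and 0 adjusted over the list alone (median log2 0.47, camera adjusted p = 0.0275, or 0.249 with an estimated correlation). Photosynthesis genes had 0 of 34 rising, 2 falling and 32 not called, with 0 and 2 adjusted over the list alone (median log2 -0.15, camera adjusted p = 0.0146, or 0.599 with an estimated correlation), the electron carrier plastocyanin PETE1 at log2 -0.56. Root cell type genes had 0 of 6 rising, 1 falling, PYK10 at log2 -1.31, and 5 not called, with 0 and 1 adjusted over the list alone (median log2 -0.70, camera adjusted p = 0.0275, or 0.146 with an estimated correlation). Wall-loosening genes had 1 of 7 rising, 3 falling and 3 not called, with 2 and 4 adjusted over the list alone (median log2 -0.51, camera adjusted p = 0.175), XTH24 at log2 -0.97. Antioxidant and oxidase genes had 1 of 11 rising, 1 falling and 9 not called, with 1 and 2 adjusted over the list alone (median log2 0.06, a downward test, camera adjusted p = 0.917), the oxidase RBOHD at log2 -0.79. Iron genes had 0 of 4 rising, 1 falling, the copper transporter COPT2 at log2 -1.28, and 3 not called, with 1 and 1 adjusted over the list alone (median log2 -0.39, camera adjusted p = 0.790). Cell cycle genes had 0 of 4 called, and 0 adjusted over the list alone (median log2 -0.13, camera adjusted p = 0.562). Calls were lost for the heat list without shoot water A, water C or PEG 3 h C (highest adjusted p = 0.104) and the phenylpropanoid list without water C or PEG 3 h C (0.0841). So were those for the photosynthesis list without water B or PEG 3 h C (0.174) and the root list without PEG 3 h B (0.430) or any water library. The photosynthesis median was then -0.09 and -0.07, and the root median -0.46 without water A and -0.40 without water C. Among genes, calls were lost for HSP17.6C without PEG 3 h C (0.0867), COPT2 without PEG 3 h B (0.0941), PYK10 without PEG 3 h C (0.117) or water A (0.162), and RBOHD without PEG 3 h A (0.0504) or water A (0.0601).

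Across all genes in shoot at 3 h, 1572 of 9207 were called, 955 higher and 617 lower, and 992 changed by log2 1 or more. The joint fit of both tissues called 914. In the authors' deposited table, the authors call 802 genes for this contrast, and all 781 of those tested here have the same sign here. Here and below, both start from the same counts, so a like sign is to be foreseen.

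**Figure D2:**
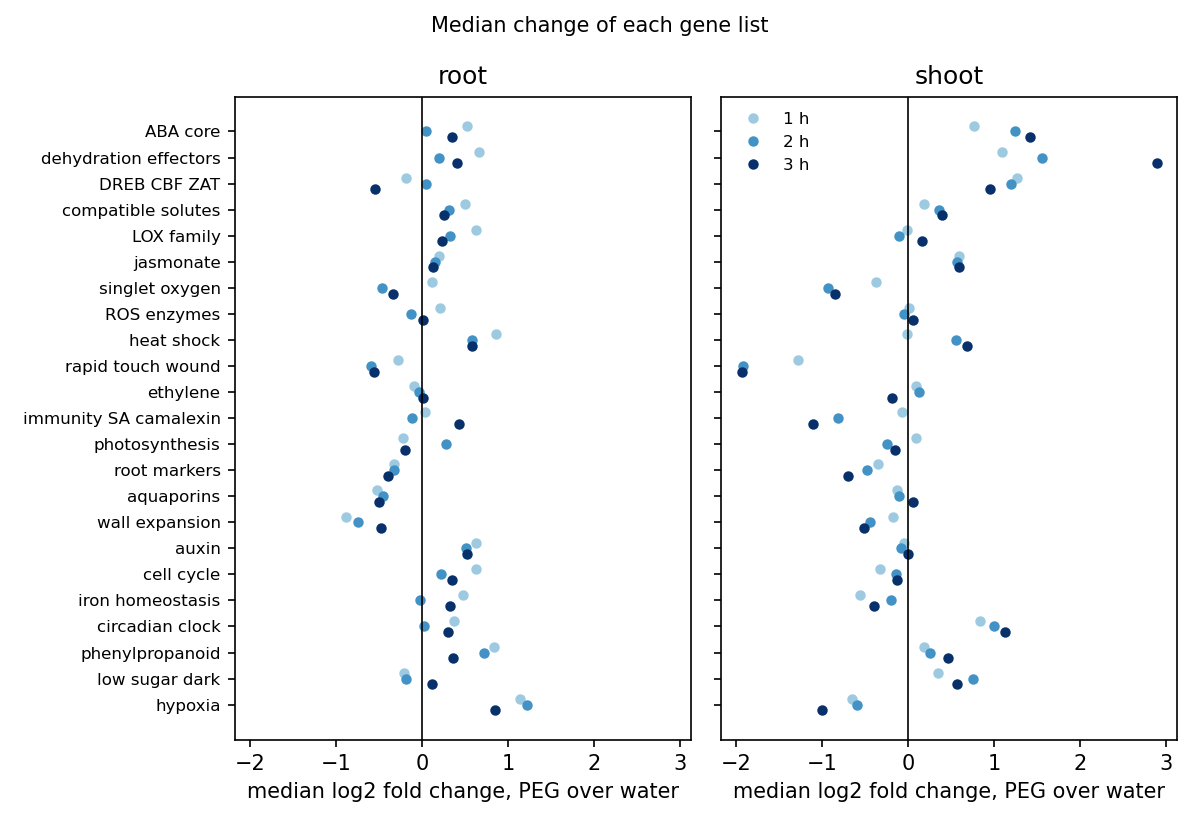
Median log2 fold change of PEG over water for each of the 23 gene lists (y axis), in root (left) and shoot (right), with 1 point per hour of PEG and 0 drawn as a line. In shoot the dehydration list moves from 1.10 at 1 h to 2.89 at 3 h and the touch and wound list from -1.28 to -1.93, and in root the dehydration list stands at 0.67 at 1 h.

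After 1 h of PEG in shoot, the 3 LSU genes, small proteins induced by sulfur shortage, were among the 5 largest rises. LSU3 rose from 1.69 ± 0.631 to 69.1 ± 24.8 (log2 5.40, SE 0.43, adjusted p = 3.06e-07), LSU1 from 2.66 ± 0.849 to 103 ± 41.9 (log2 5.32) and LSU2 from 3.92 ± 1.36 to 63.1 ± 30.8 (log2 4.05). LSU1 and LSU3 lie close in sequence, so reads may be shared. CBF3 (DREB1A) rose from 5.10 ± 0.894 to 103 ± 10.5 (log2 4.36) and ERF53 to 41.2 ± 11.8 (log2 4.15). The largest falls were AT1G33760 (log2 -3.35), SMAP1, a small acidic protein (-3.13), EXO (-2.62), AT1G32920 (-2.595) and NOI, of the RIN4 family (-2.59). RD29A stood at 703 ± 137 (log2 2.37), RD26 at 221 ± 79.8 (3.87), ABI1 at 351 ± 42.7 (2.19) and ELF4 at 72.4 ± 22.4 (2.41), all higher than in water.

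Among the 1 h shoot lists, 10 of 16 dehydration genes rose, 1 fell and 5 were not called, with 10 and 1 adjusted over the list alone (camera adjusted p = 8.65e-10, or 0.228 with an estimated correlation). Abscisic acid genes had 9 of 22 rising, 2 falling, the receptors PYL4 (log2 -0.98) and PYL6 (-0.96), and 11 not called, with 10 and 2 adjusted over the list alone (camera adjusted p = 0.000500, or 0.228 with an estimated correlation). Jasmonate genes had 9 of 21 rising, 0 falling and 12 not called, with 10 and 1 adjusted over the list alone (camera adjusted p = 0.000179, or 0.228 with an estimated correlation). ORA59, an ethylene and jasmonate integrator, rose from 17.82 ± 3.61 to 50.6 ± 6.89 (log2 1.503). Clock genes had 5 of 12 rising, 0 falling and 7 not called, with 7 and 0 adjusted over the list alone (camera adjusted p = 5.42e-06, or 0.0661 with an estimated correlation). Touch and wound genes had 1 of 8 rising, 5 falling and 2 not called, with 1 and 5 adjusted over the list alone (camera adjusted p = 0.00496, or 0.230 with an estimated correlation), ERF105 at log2 -2.40. Smaller calls were those for the DREB list (5 of 11 rising, 2 falling, 4 not called, 7 and 2 adjusted over the list alone, camera adjusted p = 0.0475, or 0.550 with an estimated correlation), the singlet oxygen list (1 of 8 rising, 4 falling, 3 not called, 1 and 4 adjusted over the list alone, camera adjusted p = 0.0475, or 0.542 with an estimated correlation) and the low-oxygen list (0 of 10 rising, 1 falling, HRA1, 9 not called, 0 and 1 adjusted over the list alone, camera adjusted p = 0.0184, or 0.228 with an estimated correlation). EXPA1, an expansin, rose (log2 1.10), and the auxin importer AUX1 (-0.99) and the catalase CAT2 (-0.83) fell. Of 9207 genes 1138 were called, 663 higher and 475 lower, 606 without shoot water A and 488 in the joint fit of both tissues. With library totals the share higher went from 58.3 to 49.6%. Calls were lost for NOI without shoot water A (adjusted p = 0.124), water B or any 1 h PEG library, and for CAT2 without water B (0.0555). Others lost were HRA1 without water A (0.151), PEG 1 h B or PEG 1 h C, and the DREB list without water B (0.0938), water C or PEG 1 h C. The singlet oxygen list was lost without PEG 1 h B (0.293) or water C, and the low-oxygen list without water C (0.205). The authors' deposited table calls 431 genes, against 694 here at log2 1 or more, and all 424 of them tested here have the same sign.

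After 2 h of PEG in shoot, LSU3 (82.1 ± 27.0, log2 5.65), CBF3 (186 ± 61.2, log2 5.21) and LSU1 (91.4 ± 27.6, log2 5.15) stood among the largest rises. AT1G70640 had 108 counts in PEG and 1 in water (ratio 62.9, counting interval 11.1 to 2509), and SDI1, a sulfur-deficiency protein, 128 and 2 (ratio 37.3, interval 10.1 to 311). The largest falls were AT1G33760 (log2 -4.10), EXO (-2.79), its relative PHI-1 (-2.69), the calcium-binding protein gene AT4G27280 (-2.56) and ZF3 (-2.55). RD29A rose to 1255 ± 71.3 (log2 3.20), PRR5 to 125 ± 4.58 (log2 2.61) and ELF4 to 175 ± 2.87 (log2 3.69). TPS11, of trehalose phosphate metabolism, rose (log2 2.16), ACS7, of ethylene synthesis, fell (log2 -1.87), and CBP60G, which drives salicylic acid synthesis, fell (log2 -1.41). Clock genes had 8 of 12 rising, 0 falling and 4 not called, with 9 and 0 adjusted over the list alone (camera adjusted p = 2.66e-11, or 0.0141 with an estimated correlation). Dehydration genes had 11 of 16 rising, 1 falling and 4 not called, with 12 and 1 adjusted over the list alone (camera adjusted p = 1.59e-11, or 0.0808 with an estimated correlation). Abscisic acid genes had 12 of 22 rising, 4 falling and 6 not called, with 12 and 4 adjusted over the list alone (camera adjusted p = 0.000234, or 0.116 with an estimated correlation). Touch and wound genes had 1 rising, 7 falling and 0 not called of 8, with 1 and 7 adjusted over the list alone (camera adjusted p = 2.16e-08, or 0.0558 with an estimated correlation). Low-sugar genes had 4 of 9 rising, 0 falling and 5 not called, with 5 and 0 adjusted over the list alone (camera adjusted p = 7.12e-05, or 0.0558 with an estimated correlation). All 34 photosynthesis genes had a negative value, though 0 rose, 1 fell and 33 were not called, with 0 adjusted over the list alone (median log2 -0.24, camera adjusted p = 7.12e-05, or 0.488 with an estimated correlation). Of 9207 genes 987 were called, 673 higher and 314 lower, with 554 in the joint fit of both tissues. The authors' deposited table calls 458 genes, against 625 here at log2 1 or more, and all 448 of them tested here have the same sign.

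The comparison of 3 h with 1 h of PEG in shoot sets no group against water, though the water libraries are part of the fit. Time of day and time in liquid differ along with the hours in PEG, so their effects cannot be told apart here. ADH1 (log2 3.35), GolS3 (3.25), COR15B (3.12), COR15A (2.98), SUS1 (2.98), XERO2 (2.34), KIN1 (2.28), ELF4 (2.104) and RD29A (1.88) were higher at 3 h than at 1 h. WRKY53, a senescence and defence factor (-2.09), PYL6 (-1.85), PYL4 (-1.76) and ORA59 (-1.67) were lower. Dehydration genes had 12 of 16 higher, 1 lower and 3 not called, with 12 and 1 adjusted over the list alone (camera adjusted p = 3.69e-16, or 0.132 with an estimated correlation). Clock genes had 2 of 12 higher, ELF4 and TOC1, 0 lower and 10 not called, with 5 and 0 adjusted over the list alone (camera adjusted p = 7.86e-05, or 0.128 with an estimated correlation). Singlet oxygen genes had 0 of 8 higher, 3 lower and 5 not called, with 0 and 3 adjusted over the list alone (camera adjusted p = 0.00215, or 0.312 with an estimated correlation). Low-oxygen genes had 2 of 10 higher, 1 lower and 7 not called, with 2 and 1 adjusted over the list alone (median log2 -0.42, mean 0.14, camera adjusted p = 0.839). Of 9207 genes 426 were called, 246 higher and 180 lower, with 114 in the joint fit. The count was 279 without shoot PEG 1 h A, 273 without PEG 3 h A and 248 without PEG 3 h B or C. TOC1 was lost without PEG 1 h A, PEG 3 h A or PEG 3 h C (highest adjusted p = 0.145). The authors' deposited table calls 133 genes, against 243 here at log2 1 or more, and all 132 of them tested here have the same sign.

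After 1 h of PEG in root, AT4G08410, a proline-rich extensin-like protein, fell from 73.1 ± 16.8 to 6.97 ± 2.57 (log2 -3.33, SE 0.38, adjusted p = 0.00690). AT4G08400 fell from 55.3 ± 20.3 to 6.39 ± 1.28 (log2 -3.08), EXT11 from 34.4 ± 8.12 to 4.34 ± 0.558 (log2 -2.97) and AT5G06630 from 82.4 ± 33.1 to 14.6 ± 3.54 (log2 -2.51), all 3 extensin-like. PRP3, a root hair wall protein, fell from 158 ± 50.2 to 39.6 ± 11.6 (log2 -2.00, adjusted p = 0.0249), and the root hair expansins EXPA18 (log2 -2.13) and EXPA7 (log2 -2.09) fell too. Other root hair genes were not called, LRX1 (log2 -2.05, adjusted p = 0.0752), COBL9 (-1.93, adjusted p = 0.103) and RHD6 (0.92). GL2, a gene of non-hair cells of the root epidermis, was not called either (-0.27). The endodermal genes CASP2 (log2 0.19) and PER64 (0.17), which build the Casparian strip, were not called. Rises were called for LSU2, from 7.03 ± 4.60 to 96.2 ± 61.9 (log2 3.74, adjusted p = 0.0322), AT1G66500, annotated to pre-mRNA cleavage (4.69 ± 0.955 to 35.0 ± 12.7, log2 2.92), and ORA47, a jasmonate-linked factor (6.85 ± 2.29 to 46.7 ± 18.1, log2 2.71). Also higher were MYB4, a repressor of phenylpropanoid genes (14.4 ± 6.05 to 103 ± 45.3, log2 2.81), and RD26 (14.7 ± 0.993 to 90.7 ± 48.8, log2 2.61, adjusted p = 0.0243). RD29A stood at 168 ± 91.0 against 87.6 ± 21.6 in water (log2 0.94, adjusted p = 0.357). The extensin genes are alike in sequence, and EXPA18 and ORA47 overlap a gene on the opposite strand.

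Of the 16 root cell type genes at 1 h, 0 rose, 3 fell, all of root hairs, and 13 were not called, with 0 and 5 adjusted over the list alone (median log2 -0.33, camera adjusted p = 0.000309, or 0.218 with an estimated correlation). Aquaporins had 0 of 19 called, with 0 and 4 adjusted over the list alone (median log2 -0.52, camera adjusted p = 6.28e-06, or 0.366 with an estimated correlation), PIP2;4 standing at 80.6 ± 15.7 against 223 ± 96.1 (log2 -1.47, adjusted p = 0.0533). Wall-loosening genes had 0 of 5 called, with 0 and 1 adjusted over the list alone (median log2 -0.88, camera adjusted p = 0.000309, or 0.218 with an estimated correlation). Upward tests were called for phenylpropanoid genes (1 of 10 rising, 0 falling, 9 not called, 5 and 0 adjusted over the list alone, median log2 0.83, camera adjusted p = 0.00162, or 0.235 with an estimated correlation). FLS1, of flavonol synthesis, rose from 41.7 ± 10.4 to 135 ± 37.7 (log2 1.68). So were heat shock genes (0 of 8 called, 1 and 0 adjusted over the list alone, camera adjusted p = 0.00254, or 0.366 with an estimated correlation) and auxin genes (0 of 12 called, 1 and 0 adjusted over the list alone, camera adjusted p = 0.00435, or 0.218 with an estimated correlation). Abscisic acid genes had 0 of 20 called, with 2 and 0 adjusted over the list alone (median log2 0.52, camera adjusted p = 0.0467, or 0.366 with an estimated correlation). That list call was lost without root PEG 1 h C (adjusted p = 0.232), PEG 1 h B, water A or water C. Low-oxygen genes had 0 of 12 called, also adjusted over the list alone (median log2 1.15, camera adjusted p = 0.0467, or 0.366 with an estimated correlation). The list call was lost without root PEG 1 h B (adjusted p = 0.239), water A or water C. Dehydration genes had 1 of 12 rising, RD26, 0 falling and 11 not called, with 1 and 0 adjusted over the list alone (camera adjusted p = 0.163). The DREB list had median log2 -0.18 (0.15 with library totals), mean 0.29 and a downward test (adjusted p = 0.219), the clock list median 0.37, mean 0.20 and a downward test (adjusted p = 0.953). The ethylene list had median -0.10 (0.16 with library totals) and mean 0.02 with a downward test (0.219), and the singlet oxygen list median 0.11 and mean -0.03 with a downward test (0.953). The salicylic acid list had median 0.03 with a downward test (0.946). Single libraries moved the medians of called lists by over 1.5 times. Without root water B aquaporins stood at -0.29, and without water A or PEG 1 h A root cell type genes at -0.54. Abscisic acid genes stood at 0.31 without water B and 0.22 without PEG 1 h C, and low-oxygen genes at 1.91 without PEG 1 h A and 0.57 without PEG 1 h B. Auxin genes, with a median of 0.625, stood at 0.26 without PEG 1 h C.

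Of 9751 genes in root, 46 were called at 1 h, 16 higher and 30 lower. DESeq2 gave 193 calls, voom with sample weights 142 and the joint fit of both tissues 226. Library totals gave 33 calls, raised the median of all genes from 0.13 to 0.41 and the share higher from 34.8 to 48.5%. The count was 2 without root PEG 1 h B, 2 without PEG 1 h C, 1 without water A, 3 without water B and 21 without water C. Each gene named as called in root at 1 h except AT4G08410 lost its call without water A, where AT1G66500 had adjusted p = 0.0579 and PRP3 0.0818, while the signs stayed. Root water B stood apart from the other root libraries, with the lowest TMM factor (0.707), the highest mitochondrial share (6.96% of counts) and the lowest mean correlation with them (0.884). The mitochondrial gene ATMG00020 alone took 6.38% of the counts of root water B. The authors' deposited table calls 301 genes, and all 298 of them tested here have the same sign.

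After 2 h of PEG in root, NCED3, of abscisic acid synthesis, rose from 1.81 ± 0.740 to 16.6 ± 10.3 (log2 3.01, SE 0.52, adjusted p = 0.0424). AT1G66500 rose to 28.0 ± 2.45 (log2 2.604), RD26 to 74.2 ± 15.1 (log2 2.33), ORA47 to 31.5 ± 5.63 (log2 2.14), FLS1 to 149 ± 34.3 (log2 1.82) and AT5G03230, a senescence regulator, from 14.5 ± 5.47 to 81.02 ± 23.9 (log2 2.49). EXT11 (log2 -2.57), AT4G08410 (-2.29), AT1G06120, a fatty acid desaturase (-2.12), PRP3 (-1.85) and the chitinase gene AT2G43590 (-1.64) fell. Low-oxygen genes had a positive value in 12 of 12, though 0 were called, with 2 and 0 adjusted over the list alone (median log2 1.23, camera adjusted p = 0.000345, or 0.180 with an estimated correlation). ADH1 stood at 66.1 ± 39.8 against 14.2 ± 5.73 in water (log2 2.17, adjusted p = 0.578). Root cell type genes had 0 of 16 rising, 1 falling and 15 not called, with 0 and 5 adjusted over the list alone (camera adjusted p = 0.000134, or 0.156 with an estimated correlation). Wall-loosening genes had 0 of 5 called, with 0 and 3 adjusted over the list alone (camera adjusted p = 0.000134, or 0.156 with an estimated correlation). Aquaporins had 0 of 19 called, with 0 and 2 adjusted over the list alone (camera adjusted p = 0.000111, or 0.449 with an estimated correlation), a call lost without root water B (adjusted p = 0.0941). Phenylpropanoid genes had 1 of 10 rising, 0 falling and 9 not called, with 4 and 0 adjusted over the list alone (median log2 0.72, camera adjusted p = 0.000111, or 0.156 with an estimated correlation). Touch and wound genes had 0 of 8 called, with 0 and 1 adjusted over the list alone (median log2 -0.59, camera adjusted p = 0.0161, or 0.188 with an estimated correlation). That call was lost without root water C (adjusted p = 0.167), water A, PEG 2 h B or PEG 2 h C. Auxin genes had 0 of 12 called, also adjusted over the list alone (median log2 0.51, camera adjusted p = 0.0177, or 0.188 with an estimated correlation). The list call was lost without root water A (adjusted p = 0.0871) or PEG 2 h C. Heat shock genes had 0 of 8 called, also adjusted over the list alone (median log2 0.58, camera adjusted p = 0.0193, or 0.449 with an estimated correlation), a call lost without root water C (adjusted p = 0.149) or PEG 2 h A. The touch median was -0.33 without water A, -0.24 without water C and -0.28 without PEG 2 h B, the auxin median 0.32 without PEG 2 h C, and the heat median 1.05 without water A. Of 9751 genes 18 were called, 12 higher and 6 lower, and library totals raised the median of all genes from 0.06 to 0.26 and lowered the share higher from 66.7 to 57.9%. Leaving out root PEG 2 h A left 3 calls, and leaving out PEG 2 h B, PEG 2 h C or any water library left 0 in edgeR's test. Each named call at 2 h rests on all 6 libraries or all but 1. DESeq2 gave 104 calls, voom with sample weights 228 and the joint fit 100. In edgeR's test 780 genes had an unadjusted p under 0.05, where 488 of 9751 would be expected by chance. PEG 2 h A had the highest share of photosynthesis genes among root libraries (0.502%), and 24 of 27 such genes had a positive value at 2 h, none called. The authors' deposited table calls 126 genes, and all 125 of them tested here have the same sign.

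After 3 h of PEG in root, AT4G08410 fell to 9.93 ± 2.62 (log2 -2.89, SE 0.37, adjusted p = 0.0107), EXT12 from 62.8 ± 25.6 to 10.2 ± 3.53 (log2 -2.62), PRP3 to 35.6 ± 9.89 (log2 -2.16), and AT4G08400 (-2.87), EXT11 (-2.72) and AT5G06630 (-2.52) fell as well. EXPA18 (log2 -1.99, adjusted p = 0.0733), EXPA7 (-1.79, adjusted p = 0.118), LRX1 (-2.19, adjusted p = 0.0711) and COBL9 (-1.73, adjusted p = 0.199) were not called at 3 h. CYP94B3, which inactivates jasmonoyl-isoleucine, fell from 118 ± 44.9 to 30.3 ± 8.64 (log2 -1.94, adjusted p = 0.0276). AT1G66500 rose to 30.5 ± 5.80 (log2 2.72), ORA47 to 44.8 ± 9.75 (log2 2.63). AT2G44130, an F-box kelch gene, rose from 30.0 ± 2.57 to 83.6 ± 18.5 (log2 1.47) and the F-box gene AUF2 from 14.5 ± 2.96 to 36.4 ± 3.17 (log2 1.33). Root cell type genes had 0 of 16 rising, 1 falling and 15 not called, with 0 and 5 adjusted over the list alone (median log2 -0.39, camera adjusted p = 3.66e-05, or 0.0969 with an estimated correlation). Aquaporins had 0 of 19 called, with 0 and 2 adjusted over the list alone (median log2 -0.50, camera adjusted p = 7.97e-06, or 0.340 with an estimated correlation). Low-oxygen genes had 12 of 12 positive and 0 called, also adjusted over the list alone (median log2 0.85, camera adjusted p = 0.0119, or 0.340 with an estimated correlation), a call lost without root PEG 3 h A (adjusted p = 0.127) or water C. The DREB list had 0 of 10 called, with 1 and 3 adjusted over the list alone (median log2 -0.55, camera adjusted p = 0.00776, or 0.400 with an estimated correlation). Wall-loosening genes had 0 of 5 called, with 0 and 1 adjusted over the list alone (median log2 -0.47, camera adjusted p = 0.00776, or 0.340 with an estimated correlation), a call lost without root PEG 3 h A (adjusted p = 0.127). Touch and wound genes had 0 of 8 called, with 0 and 1 adjusted over the list alone (median log2 -0.56, camera adjusted p = 0.00936, or 0.147 with an estimated correlation), a call lost without root water C (adjusted p = 0.0886). Auxin genes had 0 of 12 called, also adjusted over the list alone (median log2 0.53, camera adjusted p = 0.0169, or 0.340 with an estimated correlation). The list call was lost without root PEG 3 h A (adjusted p = 0.127), PEG 3 h C or water A. Phenylpropanoid genes had 0 of 10 called, with 1 and 0 adjusted over the list alone (median log2 0.37, camera adjusted p = 0.0285, or 0.400 with an estimated correlation). That call was lost without root PEG 3 h A (adjusted p = 0.275), water A or water C. Heat shock genes had 0 of 8 called, also adjusted over the list alone (median log2 0.58, camera adjusted p = 0.0308, or 0.400 with an estimated correlation). That call was lost without root PEG 3 h A (adjusted p = 0.533) or water C. Photosynthesis genes had 0 of 27 called, also adjusted over the list alone (median log2 -0.20, or 0.00 with library totals, camera adjusted p = 0.0280, or 0.688 with an estimated correlation). The list call was lost without root PEG 3 h C (adjusted p = 0.892), water B or water C. Without root water B the medians were -0.23 for root cell type genes, -0.15 for aquaporins, -0.31 for wall-loosening and 0.05 for photosynthesis genes. Without PEG 3 h A they were 0.42 for low-oxygen, -0.30 for wall-loosening, 0.23 for heat shock and -0.41 for photosynthesis genes. Without PEG 3 h C they were -0.36 for touch, 0.34 for auxin and 0.03 for photosynthesis genes. Wall-loosening genes stood at -0.82 without PEG 3 h B, and without water A heat shock genes stood at 0.89 and photosynthesis genes at -0.40. Of 9751 genes 22 were called, 5 higher and 17 lower, and library totals gave 27 calls, a median of all genes of 0.29 in place of 0.11 and a share higher of 29.6 in place of 22.7%. Leaving out root water C left 14 calls, and leaving out water A, water B or any 3 h PEG library left 0 in edgeR's test, so every named call at 3 h was lost without at least 1 library. DESeq2 gave 115, voom with sample weights 114 and the joint fit 111. In edgeR's test 763 genes had an unadjusted p under 0.05, where 488 of 9751 would be expected by chance. The authors' deposited table calls 129 genes, and all 129 have the same sign here. Between 1 h and 3 h of PEG in root, edgeR, DESeq2 and voom each called 0 genes, and the authors' deposited table calls 1. In edgeR 119 genes had an unadjusted p under 0.05, fewer than the 488 expected by chance. Camera called 4 lists between these times, with 0 genes of each called and adjusted p = 0.550 with an estimated correlation. They are the DREB (adjusted p = 0.0331), heat shock (0.0272) and phenylpropanoid lists (0.0254), lower at 3 h, and the low-sugar list (0.0490), higher at 3 h. Each of the 4 calls was lost without root PEG 1 h B, PEG 1 h C (adjusted p up to 0.985) or PEG 3 h C, and all but the DREB call without PEG 3 h B. The low-sugar median, 0.33, was -0.11 without PEG 1 h C and -0.07 without PEG 3 h C. ADH1, with the low-oxygen genes, stood at 61.6 ± 73.2 at 1 h and 31.2 ± 31.3 at 3 h.

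**Figure D3:**
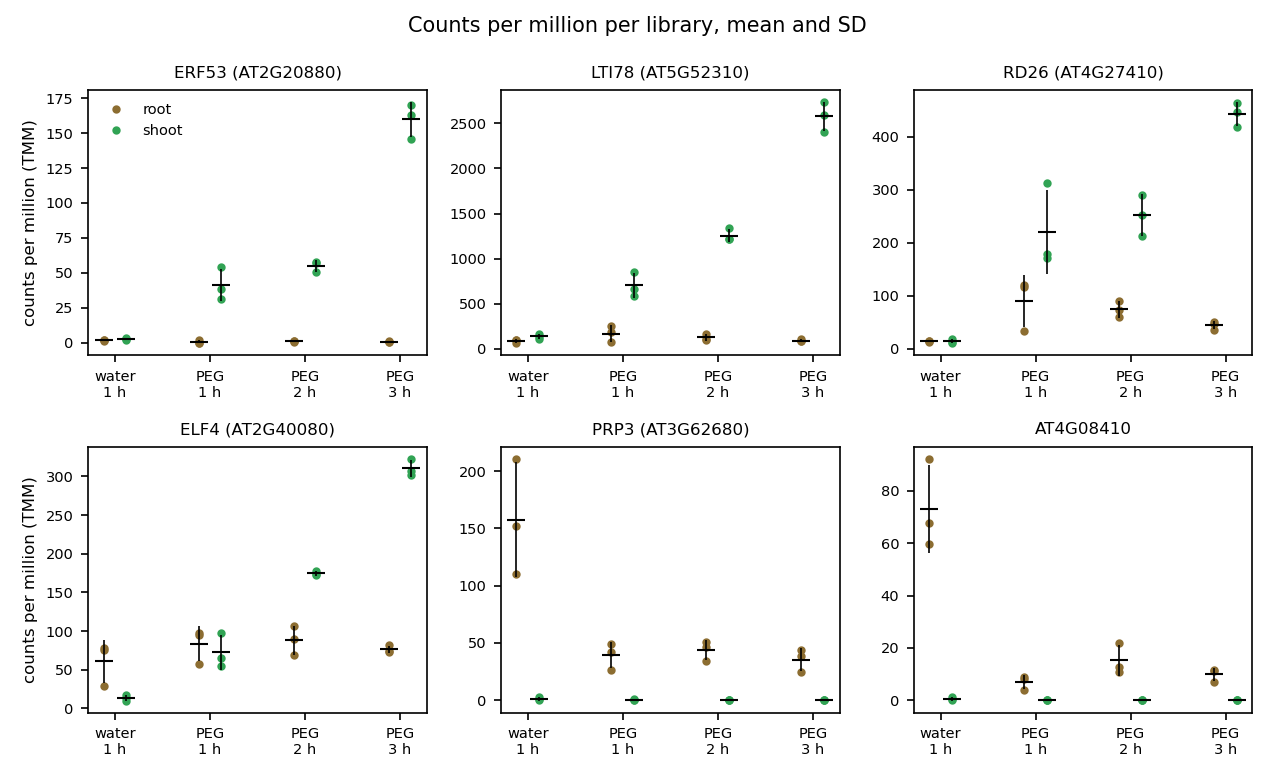
CPM (TMM) of 6 genes, picked after their values were seen, in water and after 1, 2 and 3 h of PEG in root and shoot, with 1 point per library and bars for mean ± SD over 3 libraries. ERF53 in shoot goes from 2.35 to 160 at 3 h and stays under 2 in every root library, while AT4G08410 and PRP3 are high in root water (73.1 and 158) and lower in root PEG.

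The difference between the tissues was tested as the root change minus the shoot change. Larger and smaller in root below give the sign of this difference, so a fall in shoot alone also counts as larger in root. ERF53 differed at each time, by log2 -5.60 at 1 h, -5.40 at 2 h and -7.54 at 3 h (SE 0.92, adjusted p = 1.15e-05), with 1.52 ± 0.249 in root water and 0.576 ± 0.318 in root at 3 h. AT1G51090, a heavy-metal-associated domain protein, rose in shoot at 3 h (log2 4.19) and stood at -0.95 in root (difference -5.13, adjusted p = 1.29e-07). FKF1, a photoperiod photoreceptor, rose in shoot at 2 h (log2 2.95) and stood at -1.16 in root (difference -4.07). The receptor PYL6 fell in shoot at 3 h (log2 -2.81) and stood at 0.33 in root (difference 3.11). Of 17 dehydration genes at 3 h, 0 were larger in root, 6 smaller, among them RD29A (log2 -4.20) and RD26 (-3.28), and 11 not called, with 0 and 11 adjusted over the list alone (median -1.88, camera adjusted p = 2.27e-13, or 0.00627 with an estimated correlation). Clock genes had 0 of 12 larger, 3 smaller, among them ELF4 (log2 -4.21), and 9 not called, with 0 and 8 adjusted over the list alone (median -1.40, camera adjusted p = 3.52e-08, or 0.0135 with an estimated correlation). At 2 h the estimated correlation also kept the dehydration (adjusted p = 0.0236), clock (0.00412), touch and wound (0.0341) and low-sugar (0.0264) differences. DREB, CBF and ZAT factors at 3 h had 0 of 11 larger, 5 smaller, ZAT6 at log2 -3.09, and 6 not called, with 1 and 7 adjusted over the list alone (camera adjusted p = 5.11e-07, or 0.0872 with an estimated correlation). Low-oxygen genes had 3 of 12 larger in root, PCO1 (log2 4.16), HRA1 (2.66) and HRE1 (1.96), all of which had fallen in shoot, 1 smaller and 8 not called, with 6 and 1 adjusted over the list alone (camera adjusted p = 0.00427, or 0.133 with an estimated correlation). Abscisic acid genes had 3 of 22 larger, 6 smaller and 13 not called, with 4 and 8 adjusted over the list alone (camera adjusted p = 0.00427, or 0.133 with an estimated correlation).

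Of 10967 genes, the tissue difference was called for 146 at 1 h (26 positive and 120 negative), 132 at 2 h (27 and 105) and 285 at 3 h (63 and 222). A positive difference does not mean a stronger response in root, as it can be a fall in shoot alone. With seedling pools, read from time and replicate letter, as a block, the counts were 59, 64 and 194, and with quality weights 338, 371 and 551. Library totals moved the median of all genes to 0.52, 0.19 and 0.38, and the share of positive differences from 17.81, 20.5 and 22.1% to 42.1, 31.4 and 36.9%. The 1 h count was 66 without root PEG 1 h B, 238 without root PEG 1 h C, 91 and 78 without shoot PEG 1 h A and C, and 47 and 77 without shoot water A and B. The 2 h count was 83 and 85 without root PEG 2 h B and C, 78 without root water A, 82, 85 and 76 without shoot PEG 2 h A, B and C, and 64 and 70 without shoot water A and B.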

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

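The genes and counts for root minus shoot below were singled out because the response to PEG differed between the tissues in a test of the difference itself. The number of genes called within each tissue, the clock genes in shoot, root water B and the splits of the other comparisons were looked at besides, and rest on no such test. The test of shoot tissue as the cause of the whole deviation of root water B, the test of a smaller root response in a held-out replicate and the quality weights were chosen after the result was seen, and the other tests were set before their results were known.

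The change after PEG differed between the tissues for 146 genes at 1 h, 132 at 2 h and 285 at 3 h. Of 50 splits of the libraries, 3, 5 and 5 called as many or more, with up to 235, 512 and 626 genes in another split, so chance cannot be excluded by this count. These other splits, several of them calling more than the real one, kept or mirrored the grouping of the shoot libraries and regrouped root ones, while the 133 that mixed shoot libraries called at most 4 genes. The splits therefore point to a structure of the samples, the shoot grouping by treatment. With seedling pools as a block the counts were 59, 64 and 194, and with quality weights 338, 371 and 551. Leaving out 1 library moved the 1 h count to 66 (root PEG B), 238 (root PEG C), 91 and 78 (shoot PEG A and C), and 47 and 77 (shoot water A and B). It moved the 2 h count to 83 and 85 (root PEG B and C), 78 (root water A), 82, 85 and 76 (shoot PEG A, B and C), and 64 and 70 (shoot water A and B).

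At 1 h the log2 change in root minus that in shoot was -5.60 for ERF53 (adjusted p = 0.00123), -4.20 for AT4G25433 (0.00567), -3.69 for FKF1 (0.000877) and -3.56 for RAP2.6 (0.00241). On the other side it was 5.10 for FBA7 (0.0296), 3.59 for WRKY18 (0.0404), 3.19 for AT1G33760 (0.0316) and 3.05 for maMYB (0.0150), and each of these 4 calls was lost without some single library. FBA7 overlaps AT4G26510 and AT4G26530 on the same strand, so reads counted for it may come from these genes. With the pool block AT1G33760 (adjusted p = 0.113), FBA7 (0.104) and WRKY18 (0.0509) were not called. FBA7 was not called without root PEG B (adjusted p = 0.0751), root water A (0.142), B (0.0509) or C (0.0584) or shoot water A (0.0692), and maMYB without root PEG B (0.0566) or shoot water A (0.0733). WRKY18 was not called without root PEG B (0.171), root water A (0.0646), B (0.106) or C (0.0597), shoot PEG A (0.107), B (0.0702) or C (0.0706), or shoot water A (0.175) or B (0.0600). AT1G33760 was not called without root PEG C (0.202), root water C (0.0739), shoot PEG B (0.0675), or shoot water A (0.0738), B (0.0642) or C (0.0548).

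At 2 h the difference was -5.40 for ERF53 (adjusted p = 0.000567), -4.93 for AT4G25433 (0.000426), -4.07 for FKF1 (0.000211) and -4.01 for AT1G07985 (0.00891). It was 3.45 for HRA1 (AT3G10040, 0.00111), 4.89 for AT4G33560 (0.0476), 2.68 for AT5G01015 (0.0153) and 2.62 for AT1G70990 (0.0356), the last 3 of them lost without some single library. With the pool block AT1G70990 (adjusted p = 0.0553) and AT4G33560 (0.107) were not called. AT5G01015 was not called without root PEG B (0.0893) or root water A (0.118). AT1G70990 was not called without root PEG B (0.112), root water A (0.0923) or C (0.0703), shoot PEG B (0.117) or C (0.118), or shoot water A (0.0586), B (0.0862) or C (0.105). AT4G33560 was not called without root PEG A (0.148), root water A (0.112), B (0.133) or C (0.138), shoot PEG A (0.129), B (0.0738) or C (0.143), or shoot water A (0.113) or C (0.110).

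At 3 h the difference was -7.54 for ERF53 (adjusted p = 1.15e-05), -6.17 for AT4G25433 (8.64e-06), -5.13 for AT1G51090 (1.29e-07) and -5.12 for AT4G28140 (1.75e-05). It was 3.91 for AT1G33760 (0.00464), 3.65 for AT1G70990 (0.01001), 3.14 for SAUR36 (0.0171) and 3.11 for PYL6 (3.09e-05). SAUR36 was not called without shoot PEG B (adjusted p = 0.0717) or C (0.0554) or shoot water C (0.0923).

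Fewer genes were called in root than in shoot at each PEG time, 22 against 1572 at 3 h, and with every library thinned to 1203312 counts, 10 against 718 at 3 h, a ratio of 71.8 that argues against sequencing depth. Without root water B edgeR called 0 root genes, with 558 at unadjusted p under 0.05 (488 expected by chance with all libraries). Shoot without 1 of its water libraries, at the same number of libraries, had 1212 to 1758 calls, which argues against that 1 root library as the cause. A larger spread in root (biological coefficient of variation 34.2% against 17.2%) lowers the count. Genes were also chosen in shoot without 1 replicate and measured in that replicate, where the median root change was 13.5, 29.8 and 7.51% of the shoot change. These values argue against an equal root response of the same genes that spread alone hides. A smaller response in root of the genes that respond in shoot is therefore a candidate explanation. Because a shoot call picked the genes, root responses of other genes, hidden by spread, would not be seen. Whether spread alone explains the low root count therefore cannot be decided by this test. Over the 1388 genes called in shoot at 3 h and tested in root the medians were 1.18 in shoot and 0.23 in root, a ratio of 19.4% that the choice of genes in the same libraries lowers, with a 95% interval of 16.6 to 22.3% that covers the spread over genes and not over libraries. Of the 258 genes called for the difference and in shoot, 248 (96.1%) changed less in root, but as a shoot call picked them, a smaller response of root genes at large and this selection cannot be told apart.

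Clock genes differ between PEG and water in shoot, with 8 of the 12 tested called at 3 h. The explanation tested was time of day, as water was sampled at 1 h only. Of these 8 genes, 5 were already called in the same direction at 1 h. By the source names PEG and water libraries had the same time of exposure there, which argues against time of day as the whole cause. If the sample titles hold, which code the water libraries as time 0, the times differ and this test cannot decide. In either case time of day stays open for the other 3 genes and for the size of the later changes. An effect of PEG on the clock may contribute and was not tested apart from this.

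Root water B stood apart from water A and C: among the 976 genes with the highest counts, the SD of its log2 deviation was 0.81 against 0.22 for A minus C, a ratio of 3.77 that argues against low counts of single genes as the cause. Its photosynthesis genes lay higher by a median of 0.77 (SD 0.43 over 27 genes, against -0.06 for all genes). Its share of chloroplast genome counts was lower, at 0.00335% against 0.00976% in A and 0.0113% in C. A trace of shoot tissue, of 0.317% by the summed count share of the photosynthesis list, may account for the photosynthesis genes. It would not lower the chloroplast share. Such a mixture gave 3.57% of the observed SD in the 976 genes, which argues against it as the cause of the whole deviation. The deviation had a rank correlation of -0.254 with gene length, between the bounds set for and against a length bias, so a length bias and other sources of the deviation cannot be told apart. No biological explanation was tested, as the labels give nothing that sets this replicate apart.

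The splits of 3 against 3 libraries number 10, too few for a share under 0.05, and in each case below 1 of the 10, the real one, reached the real count unless stated. The real counts and the highest of the other splits were 46 and 0 at 1 h, 18 and 0 at 2 h and 22 and 0 at 3 h in root, and 1138 and 0, 987 and 0 and 1572 and 0 in shoot. For 3 h against 1 h they were 426 and 2 in shoot and 0 and 0 in root, where all 10 splits reached the real count of 0, and for root against shoot in water 5845 and 13.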

How the results depend on the processing

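Sample quality weights, scaling by library totals, and leaving out root water B and root PEG 2 h A together were chosen after the results were seen, as were the list tests without these 2 libraries and the tests of lists and list members with each library left out. Alternatives planned for the case that only normalized values were available were not run, since counts were. The cause of each change below was not tested, except where fewer libraries or a bound on the fold change is the setting itself.

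DESeq2 called 193, 104 and 115 genes in root at 1, 2 and 3 h, against 46, 18 and 22 with edgeR, with all of edgeR's genes among them, and 341 against 146 for the tissue difference at 1 h (134 of them shared). Quality weights gave 142, 228 and 114 in root and 338, 371 and 551 for the tissue differences. The joint fit of both tissues gave 226, 100 and 111 in root, 488, 554 and 914 in shoot, and 114 for 3 h against 1 h in shoot. A fit of the 6 libraries compared gave 611 in shoot at 1 h and 5, 0 and 0 in root, the last 2 with 619 and 514 genes at unadjusted p under 0.05. Over the 9751 genes of the root fit, 488 would be expected there by chance. Without root water B and root PEG 2 h A, edgeR called 0 genes in root at 2 h, with 672 at unadjusted p under 0.05. Requiring an absolute log2 fold change of at least 1 left 694, 625 and 992 genes in shoot, and 243 for 3 h against 1 h. A block of seedling pools gave 59 and 64 genes for the tissue differences at 1 and 2 h, and library totals gave 76 at 1 h. Of the 59 list calls in PEG against water, camera with an estimated correlation kept 2, the clock in shoot at 2 and 3 h.

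With each library left out in turn, counts ran from 1 to 43, 0 to 3 and 0 to 14 in root at 1, 2 and 3 h. They ran from 606 to 1338, 712 to 847 and 1202 to 1758 in shoot, and from 248 to 487 for 3 h against 1 h in shoot. For 3 h against 1 h in root the count was 0 with every tool and setting (edgeR 119 genes at unadjusted p under 0.05, DESeq2 231, voom with weights 167). The tissue differences ran from 47 to 238, 64 to 121 and 200 to 277, and root against shoot in water from 5242 to 5712. Where the root count was 0 with 1 library left out, 525 to 900 genes had an unadjusted p under 0.05. With all libraries 488 root genes would be expected there by chance, so the lower of these counts lie near chance. Over all libraries left out, named genes kept direction and side of the threshold in 1091 cases, lost the call in 250, gained it in 3 and reversed in 21. Of the list members called with all libraries, 0 of 6, 0 of 4 and 0 of 2 in root at 1, 2 and 3 h, and 45 of 70, 65 of 88 and 82 of 116 in shoot, were called with every single library left out.

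Reversals among named genes with 1 library left out were in values that were not called: log2 -0.0816 to 1.90 for FER3 in root at 1 h, -0.0142 to 0.39 for LOX1 in root at 3 h. LOX1 in shoot ran from -0.22 to 0.32, -0.31 to 0.20 and -0.0440 to 0.47 at 1, 2 and 3 h. LOX2 in shoot at 1 h ran from -0.10 to 0.33. LOX4 ran from -0.11 to 0.42 and -0.24 to 0.11 in root at 1 and 3 h and from -0.26 to 0.10 and -0.0340 to 0.24 in shoot at 1 and 3 h. LOX6 in root ran from -0.73 to 0.0905 at 2 h and -0.81 to 0.43 at 3 h. LOX4 in root at 3 h reversed to 0.0136 with no filter, 0.0355 with the letter block, 0.30 with quality weights, 0.18 with library totals, 0.11 without the 2 libraries and 0.00931 in the 6-library fit. LOX1 in shoot at 1 h reversed to 0.00581 with DESeq2, 0.00571 with no filter, 0.0214 with the letter block, 0.0325 with quality weights and 0.0853 in the joint fit, and LOX4 there to 0.00593 with quality weights. LOX6 in root at 3 h reversed to 0.21 with library totals and LOX1 there to -0.0233 without the 2 libraries. Over the lists, the estimated correlation left 154 results as they were and ended 99 calls, and fry left 192, ended 44, added 7 and reversed 10.

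Adjusted p of the lists whose direction reversed under fry was 0.865 for singlet oxygen, 0.9754 for salicylic acid and camalexin and 0.865 for the clock in root at 1 h. It was 0.692 for reactive oxygen enzymes and 0.828 for iron in root at 3 h, and 0.957 for reactive oxygen enzymes in shoot at 3 h. For 3 h against 1 h it was 0.981 for ethylene and 1.00 for hypoxia in root, and 0.748 for reactive oxygen enzymes and 0.298 for hypoxia in shoot. Without the 2 libraries the lists that reversed had 0.398 for photosynthesis in root at 1 h, 0.794 for reactive oxygen enzymes and 0.652 for the clock at 2 h, and 0.640 for reactive oxygen enzymes, 0.335 for iron and 0.384 for low sugar at 3 h.

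Size factors by RLE, a filter at a mean of 10 counts, no filter, organelle genes left out and the letter block kept each count of genes within 1.5 times. Replicate letters share only a letter, not a known batch, and the root and shoot libraries of a letter were treated as 1 pool in the pool block alone. In a check of the letters across times, r was positive in all 6 pairs of root letter C (0.07 to 0.68). For the other letters of either tissue it took both signs. On the first principal component of root, PEG C lay at 43.5, 42.2 and 42.5 at 1, 2 and 3 h, and water C at 0.52. A source of variation shared by root PEG C libraries therefore cannot be excluded. In simulated data 7% of 2-fold changes were recovered in root at 3 h against 47% in shoot, so most 2-fold changes in root would be missed.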

Other observations

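Genes of the mitochondrial genome took 2.41 to 6.96% of the counts in the 12 root libraries and 0.170 to 0.2999% in the 12 shoot libraries. Most of this came from 1 gene, ATMG00020, with 2.14 to 6.38% of counts in root and 0.156 to 0.277% in shoot. Left out of the fit, organelle genes changed no count of called genes beyond 1.5 times. TMM factors ran from 0.707 to 1.28 in root and from 0.828 to 1.11 in shoot.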
